A study of Mus musculus with 6 samples.

How the data were processed

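RNA was measured by sequencing in 6 libraries from ovaries of C57BL/6 mice at E18.5, of which 3 are labelled WT and 3 are labelled Hnrnpl-null. Hnrnpl encodes a heterogeneous nuclear ribonucleoprotein that binds RNA and regulates splicing. Per the labels' protocols, ovaries were treated with Liberase and DNase to give single cells, and libraries were made with a fast RNA-seq kit from total RNA. The labels give the cell type as oocyte and the tissue as ovary. They name no sort that would remove somatic cells. Nothing in the labels says which libraries came from separate animals, so p-values measure the spread between these libraries, which may in part be technical. The series design also names postnatal day 1 ovaries, which are not analysed here.

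The authors deposited 1 table of raw gene counts, with 25239 rows and 1 column per library, and per the file headers its layout is that of featureCounts. Per the submitters' processing notes, STAR 2.7.11a, HISAT2 2.2.1, featureCounts 2.0.6 and the genome build mm10 were used, with no role or order given. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Per the file headers, the authors also gave each gene's exon coordinates and exonic length. Every row names a gene, no column belongs to another sample, and 0 mitochondrially encoded genes are in the table. Gene symbols are those of the table. Of the symbols in the gene lists, 7 were matched to the table through synonyms of the RefSeq gene table of GRCm38.p6.

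Some properties of the deposited counts bear on their precision. Of the counts between 1 and 20, 93.4% to 98.4% per library were even numbers, as when both mates of a read pair are counted, so a read pair appears to be worth 2 counts and the totals overstate the number of fragments. For that reason the limit set by a count of 0 was taken as 3 read pairs, or 6 counts, over a group. It covers counting error only, because reads carry no molecular identifiers. Rn45s, the 45S pre-ribosomal RNA, took 18.6% to 86.1% of the counts. It left between 1757572 and 10980179 counts for all other genes. Genes whose exons overlap those of another gene cannot be told apart without a known strand setting. Adult globin genes (Hba-a1, Hba-a2, Hbb-bs and Hbb-bt) are each annotated over a second overlapping gene model and are listed at 0 in all 6 libraries, so they carry no information on red cells here.

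Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM factors, glmQLFit and glmQLFTest, two-sided), with genotype as the only term and all 6 libraries in the fit. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The filter left 14849 genes. Levels are CPM, computed on the TMM-scaled library size, given as mean ± SD over 3 libraries. Standard errors of log2 fold changes were derived from the F statistic of the same test. Gene lists were fixed before the data were examined (24 lists of processes, cell types and RNA quality) and tested with limma 3.58.1 camera on voom values, with a preset inter-gene correlation of 0.01. The 23 lists with members in the table were adjusted together. The list of mitochondrially encoded genes had no member to test. Several lists share genes, among them the germ cell identity and piRNA lists. Estimated correlations and fry were run beside it. The test was tried on simulated counts drawn from the means, sizes and dispersions of these libraries. The draw did not model the even counts or genes high in 1 library only. Of the genes changed 4-fold it called 86.4% (57 of 66), of those changed 2-fold 55.2% (37 of 67) and of those changed 1.5-fold 14.9% (10 of 67). Among its calls, 8 were of unchanged genes, or 7.14%.

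The genes named in the text were chosen by a rule fixed at the same time as the lists. It takes Hnrnpl, and the 8 largest rises and 8 largest falls among called genes with a mean CPM of at least 5 in the higher group, groups that do not overlap, and a symbol other than a gene model or pseudogene. It adds up to 3 members with the smallest p of each list that was called or had at least 2 called members. Other genes named were chosen after their values were seen, as were 7 added lists of blood, liver and bone cells (granulocyte-monocyte progenitor, mast cell, neutrophil secondary granule, hepatocyte, megakaryocyte, lymphoid and osteoblast). The alternatives planned in advance were DESeq2 1.42.0, limma-voom, other scalings, other filters, leaving out each library, the replicate number of the titles as a block, removal of the trend with gene length, robust dispersions and stricter thresholds. The alternatives added after seeing the data were leaving out the Rn45s row (with TMM or with totals alone), leaving out both libraries richest in Rn45s, halving the counts, and voom with sample weights. Some genes that the rule or the text would name are not reported here. Splicing was not analysed, since counts per gene do not show it.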

Results

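Gene expression was compared between 3 WT ovary libraries and 3 ovary libraries labelled Hnrnpl-null, all from mice at E18.5, when oocytes are in late meiotic prophase and germ cell cysts are beginning to break into primordial follicles. The series title places the study in germ cell integrity and the founding of the primordial follicle pool. Total counts were 22401419, 11653095 and 8949781 in WT replicates 1 to 3 and 12786602, 14090992 and 12689943 in Hnrnpl-null replicates 1 to 3. Rn45s, the 45S pre-ribosomal RNA, took 83.0% of the counts in WT replicate 1 and 86.1% in Hnrnpl-null replicate 3, against 18.6% to 36.0% in the other libraries. Counts outside Rn45s were 3818414 in WT replicate 1 and 1757572 in Hnrnpl-null replicate 3, against 5727264 to 10980179 in the others. Replicates of 1 group differed by more than counting noise in each pair, with a chi-square per degree of freedom of 5.46 or more on halved counts, so no pair was treated as 1 library deposited again. That does not show that they came from separate animals.

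**Figure D1:**
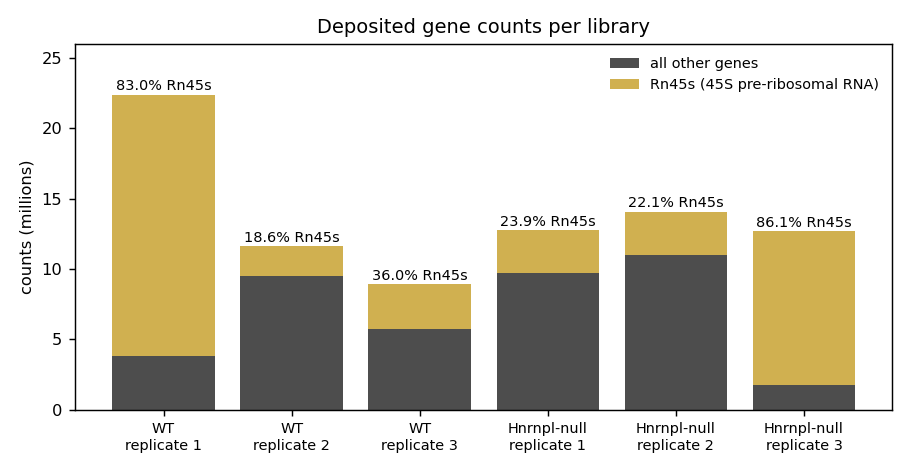
Deposited counts per library (y axis, in units of 1e6) for the 3 WT and 3 Hnrnpl-null libraries (x axis), split into Rn45s and all other genes, with the share of Rn45s above each bar. WT replicate 1 and Hnrnpl-null replicate 3 hold 83.0% and 86.1% Rn45s.

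Hnrnpl itself (chromosome 7, 28810890 to 28822266, mm10, plus strand) did not separate the groups. Its level was 172, 169 and 145 CPM in WT replicates 1 to 3 and 166, 173 and 213 CPM in Hnrnpl-null replicates 1 to 3. The means were 162 ± 14.8 (SD, n = 3) and 184 ± 25.5 CPM (SD, n = 3). The ratio of Hnrnpl-null to WT was 1.13, with a 95% interval of 0.936 to 1.37, and the edgeR quasi-likelihood test gave an adjusted p of 0.50. The interval excludes a fall of the gene's summed count to below 0.936 of WT. The counts run over all exons of the gene and all cells of the sample, and the labels do not say which exons were removed or in which cells. The titles of the libraries labelled Hnrnpl-null carry the abbreviation CKO, which the labels do not explain. The Hnrnpl count therefore does not check the labels, and the groups below are those of the labels.

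The libraries labelled Hnrnpl-null had lower levels of germ cell transcripts and higher levels of leukocyte transcripts than WT. Of 14849 genes tested, 663 were called by edgeR at an adjusted p below 0.05, 397 higher and 266 lower in the libraries labelled Hnrnpl-null. An unadjusted edgeR p below 0.05 was reached by 2746 of the 14849, the share to set beside such counts in the lists below. Of the called genes, 662 had groups that did not overlap, and among all tested genes 3797 (25.6%) had separate groups, where chance gives 10%. Without the 2 libraries richest in Rn45s, 832 genes were called, 514 higher and 318 lower, and 544 of them were among the 663. Leaving out 1 library gave 370, 257 and 335 genes without WT replicates 1, 2 and 3 and 389, 249 and 853 genes without Hnrnpl-null replicates 1, 2 and 3. Hnrnpl-null replicate 3 stood apart from its group, at 112 on the first principal component of log CPM (53.7% of the variance) against -9.38 and -5.91, and its correlation with the other 2 was 0.912 and 0.911 against 0.972 between them. WT replicate 1 stood apart on the second component (20.8%), at 54.4 against 4.51 and 6.65 in WT replicates 2 and 3. Its correlation with those 2 was 0.951 and 0.946, against 0.967 between them.

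Oocyte transcription factors of primordial follicle formation were lower in the libraries labelled Hnrnpl-null. Nobox (chromosome 6, 43303674 to 43309554), a homeobox factor of oocytes, fell from 20.8 ± 2.7 to 2.25 ± 0.347 CPM (SD, n = 3 each), a log2 fold change of -3.25 ± 0.23 (SE) with an edgeR adjusted p of 2.5e-06. Sohlh1 (chromosome 2, 25842997 to 25847248), a basic helix-loop-helix factor of early oocytes, fell from 24.0 ± 1.22 to 4.93 ± 1.05 CPM. Lhx8, a LIM homeobox factor, fell from 25.6 ± 1.88 to 5.12 ± 1.65 CPM, and Figla, which activates zona pellucida genes, fell to 29.9% of WT, with its call lost without Hnrnpl-null replicate 2 (edgeR adjusted p = 0.053). Uchl1, a deubiquitinase abundant in oocytes, fell from 62.8 ± 1.31 to 20.6 ± 1.75 CPM, with exons that overlap an antisense gene. Of the 20 tested members of the list of oocyte genes of primordial follicle formation and growth, 9 were lower and 11 were not called. Without Hnrnpl-null replicate 2, 6 were lower, and 7 were lower without WT replicate 2 or 3 or Hnrnpl-null replicate 1. Adjusted over the list alone, 12 were lower. The median log2 fold change of the list was -1.27 (camera adjusted p = 2.4e-14). Kit, the receptor for the ligand made by Kitl, was 97.0 ± 4.93 CPM in WT and 88.7 ± 3.93 CPM in Hnrnpl-null and was not called. Counts run over all cells of the sample, so these levels do not show whether Kit was kept in oocytes. Gdf9, an oocyte growth factor, was at 2.51 ± 0.833 CPM in WT and 2.38 ± 0.475 CPM in Hnrnpl-null and was not called.

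Genes of the piRNA pathway, which silences transposons in germ cells, were also lower. Tdrd1 (chromosome 19, 56826209 to 56870012), a Tudor scaffold protein, fell from 59.3 ± 5.31 to 12.8 ± 3.08 CPM, a log2 fold change of -2.15 ± 0.16 (edgeR adjusted p = 3.8e-06). Piwil2, a piRNA-binding Argonaute, fell from 83.9 ± 2.52 to 31.0 ± 2.80 CPM, and Mov10l1, an RNA helicase of the same pathway, fell from 101 ± 7.89 to 38.0 ± 7.50 CPM. Of 20 tested members of this list, 13 were lower and 7 were not called, and 16 were lower adjusted over the list alone (median log2 fold change -1.20, camera adjusted p = 6.9e-20). Without Hnrnpl-null replicate 2, 8 were lower. The germ cell identity list had 8 of 17 members lower (10 adjusted over the list alone), with a median of -0.84 (camera adjusted p = 2.4e-10), and 4 were lower without WT replicate 3 or without Hnrnpl-null replicate 2. Within it Ybx2, a germ cell RNA-binding protein, fell from 41.7 ± 4.60 to 10.6 ± 2.05 CPM. Dppa3, a maternal factor, fell from 3.74 ± 1.53 to 0.0535 ± 0.0465 CPM. The lower level rests on 2, 2 and 0 counts in Hnrnpl-null replicates 1 to 3, so the size of the fall is imprecise. The germ cell markers Ddx4 and Dazl fell to 53.4% and 56.2% of WT. The Ddx4 call was lost without any 1 of the WT libraries or Hnrnpl-null replicate 2 (edgeR adjusted p of 0.066 to 0.16), and the Dazl call without WT replicate 3 or Hnrnpl-null replicate 1 or 2 (edgeR adjusted p of 0.054 to 0.073).

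Meiotic genes formed another part of the falls. Smc1b, a meiotic cohesin subunit, fell from 47.7 ± 6.42 to 17.4 ± 4.13 CPM. Tex15, needed for meiotic recombination, fell from 193 ± 25.3 to 77.5 ± 19.1 CPM. Gm4969, which the RefSeq table gives as Meiosin, a regulator of meiotic entry, fell from 39.0 ± 2.19 to 15.4 ± 1.26 CPM, with exons that overlap those of Six5. Sycp3, an axial element protein of the synaptonemal complex, fell to 26.8% of WT and the cohesin Rec8 fell to 20.9% of WT. Of 38 tested members of the list of synaptonemal complex and recombination genes, 15 were lower and 23 were not called, and 7, 8 and 9 were lower without WT replicate 2, WT replicate 3 and Hnrnpl-null replicate 2. Adjusted over the list alone, 18 were lower (median log2 fold change -0.96, camera adjusted p = 2.6e-15). The 88 distinct genes tested in these 4 germ cell lists held 40 lower calls, with a median log2 fold change of -1.03. Without WT replicate 2, WT replicate 3 and Hnrnpl-null replicate 2 the lower calls were 25, 25 and 24, and over the 6 fits that left out 1 library the median was -1.13 to -0.93. Without the 2 libraries richest in Rn45s the median was -1.04, with 41 of 92 lower. The 4 lists were called in each of the 16 other settings of the list tests, and with an estimated correlation each had an adjusted p of 0.026. The list of primordial germ cell and pluripotency genes was not called, with a median of -0.16 (camera adjusted p = 0.37). Leaving out 1 library gave a median of -0.45 to -0.11 (camera adjusted p of 0.19 to 0.40). Without the 2 libraries richest in Rn45s it was -0.53 (camera adjusted p = 0.21). The filter left 9 of the 19 genes of the list. Of its 9 tested members, 0 were called by edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone, and 0 had an unadjusted p below 0.05.

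**Figure D2:**
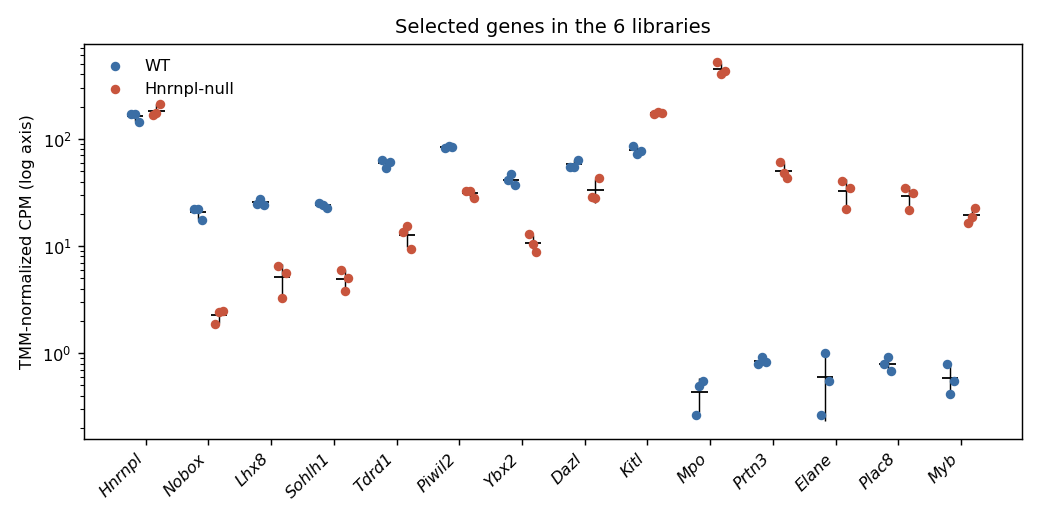
TMM-normalized CPM on a log axis (y) of 14 genes (x) in the 3 WT (blue) and 3 Hnrnpl-null (red) libraries. Points are libraries, horizontal bars are means and vertical bars are ± 1 SD. Nobox, Sohlh1 and Tdrd1 lie lower in each Hnrnpl-null library, Mpo and Prtn3 lie higher, and the groups overlap for Hnrnpl.

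The largest rises included proteins of myeloid granules. Mpo (chromosome 11, 87793784 to 87804412), the myeloperoxidase of primary granules, was at 0.437 ± 0.153 CPM in WT and 451 ± 63.9 CPM in Hnrnpl-null (SD, n = 3 each), a log2 fold change of 9.88 ± 0.22 (SE, edgeR adjusted p = 7.8e-12). The granule proteases Ctsg, Prtn3 and Elane rose from 0.115 ± 0.135 to 33.5 ± 6.09 CPM, from 0.843 ± 0.0624 to 50.5 ± 9.23 CPM and from 0.603 ± 0.369 to 32.4 ± 9.38 CPM. Ms4a3 had no counts in WT and 11.6 ± 1.09 CPM in Hnrnpl-null, a mean of 89.1 times the limit of 6 counts over the 3 WT libraries. Nkg7 also had no counts in WT and was at 6.10 ± 3.44 CPM, at least 47.0-fold higher. Plac8 rose from 0.797 ± 0.112 to 29.2 ± 6.83 CPM, and Myb, a transcription factor of blood progenitors, rose from 0.585 ± 0.190 to 19.3 ± 3.01 CPM. In the preset list of macrophage and other leukocyte genes, 4 of 16 tested members were higher (6 higher adjusted over the list alone), with a median of 0.58 (camera adjusted p = 2.6e-05). Those called were Coro1a, Laptm5, Ptprc and Cx3cr1, of which Ptprc encodes the leukocyte common antigen CD45. The Cx3cr1 call was lost without WT replicate 2 or Hnrnpl-null replicate 2 (edgeR adjusted p of 0.060 to 0.082). Coro1a rose from 3.99 ± 0.498 to 32.5 ± 7.75 CPM, and Laptm5, a lysosomal protein of blood cells, rose from 11.5 ± 1.57 to 41.3 ± 2.94 CPM. The macrophage genes C1qa and Lyz2 were at 6.68 ± 1.18 and 9.82 ± 1.35 CPM in WT against 5.60 ± 1.04 and 9.86 ± 5.84 CPM in Hnrnpl-null and were not called. The erythroid list had 4 tested members, none called, with a median of 0.88. Of these, 2 had an unadjusted p below 0.05, 2 were higher adjusted over the list alone, and DESeq2 and limma-voom each called 2 higher, as did edgeR without Hnrnpl-null replicate 3. Its camera adjusted p was 0.019, and its adjusted p was 0.32 with an estimated correlation and 0.053 to 0.24 when WT replicate 1 or 3 or Hnrnpl-null replicate 1 or 2 was left out. Alas2, the erythroid enzyme of haem synthesis, was at 192% of WT and was not called (edgeR adjusted p = 0.050).

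Among the 8 largest falls, 4 took their size from WT replicate 1. Kif17, Eif4ebp2, Map7d2 and Kbtbd11 had 1480 ± 2558, 4072 ± 6904, 130 ± 198 and 19.4 ± 25.3 CPM in WT, where the SD exceeds the mean. Without WT replicate 1 their log2 fold changes went from -9.59, -6.67, -3.78 and -3.02 to -0.74, -1.13, -0.81 and -1.01, and of the 4 only Eif4ebp2 was then called (edgeR adjusted p = 0.0077). The 4 calls were also lost without any 1 of the Hnrnpl-null libraries (edgeR adjusted p of 0.050 or more). The other 4 were Nobox, Pramef12, Vil1 and Ccdc201. Pramef12 fell from 13.4 ± 2.58 to 1.39 ± 0.743 CPM. Vil1, which encodes the actin-bundling protein villin and whose exons overlap those of Usp37, fell from 7.73 ± 0.906 to 0.911 ± 0.718 CPM. Ccdc201 fell from 8.73 ± 1.74 to 1.15 ± 1.01 CPM.

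Interferon-stimulated genes were lower as a list, with a median log2 fold change of -0.84 (camera adjusted p = 1.8e-05, and adjusted p = 0.045 with an estimated correlation). Of 22 tested members, 4 were lower, Bst2 among them, 1 was higher (Gbp2) and 17 were not called, and adjusted over the list alone 5 were lower and 1 was higher. Without any 1 of the WT libraries 2 were lower. Bst2, which encodes the antiviral protein tetherin, fell from 18.8 ± 0.349 to 7.99 ± 1.78 CPM. Gbp2, a guanylate-binding protein, rose from 10.8 ± 0.248 to 20.1 ± 4.78 CPM, but its call was lost without any 1 of the WT libraries or Hnrnpl-null replicate 2 (edgeR adjusted p of 0.067 to 0.16).

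Genes of DNA replication and mitosis were higher as a list, with a median of 0.34 (camera adjusted p = 1.8e-05, and adjusted p = 0.045 with an estimated correlation). Of 30 tested members, 5 were higher and Cenpf was lower, and adjusted over the list alone 11 were higher and 3 lower. The higher calls were 2 without WT replicate 1 or 2 and 3 without Hnrnpl-null replicate 1 or 2. The Cenpf call was lost without WT replicate 3 or Hnrnpl-null replicate 2 (edgeR adjusted p of 0.083 to 0.097). The replicative helicase subunits Mcm7 and Mcm3 rose from 31.2 ± 3.40 to 52.7 ± 5.32 CPM and from 40.5 ± 4.29 to 62.8 ± 1.94 CPM. Rrm2, a subunit of ribonucleotide reductase, rose from 13.1 ± 1.77 to 25.7 ± 4.17 CPM. The Mcm3 call was lost without WT replicate 1 and the Rrm2 call without WT replicate 2 (edgeR adjusted p = 0.055 and 0.057). In the list of integrated stress and unfolded protein response genes, 5 of 25 members were higher by edgeR (10 higher and 1 lower adjusted over the list alone), and 3 were higher without any 1 of the WT libraries or Hnrnpl-null replicate 2. Its median was 0.25 (camera adjusted p = 1.6e-04, but adjusted p = 0.13 with an estimated correlation). Psat1 and Phgdh, enzymes of serine synthesis, rose from 17.5 ± 1.29 to 37.7 ± 2.51 CPM and from 25.2 ± 5.17 to 46.5 ± 7.83 CPM, though the Phgdh call was lost without WT replicate 2 (edgeR adjusted p = 0.066). Xbp1, a transcription factor of the unfolded protein response, rose from 34.6 ± 1.10 to 53.6 ± 2.68 CPM.

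Of 30 p53 target genes tested, Aen, an exonuclease, was lower, the same count as adjusted over the list alone (median 0.003, mean -0.022, camera adjusted p = 0.82). The cell cycle inhibitor Cdkn1a was at 26.7 ± 8.33 CPM in WT and 36.8 ± 2.99 CPM in Hnrnpl-null and was not called. Of 31 apoptosis regulators, 0 were called by edgeR, DESeq2 or limma-voom and 0 adjusted over the list alone, while 8 had an unadjusted p below 0.05 (median 0.09, camera adjusted p = 0.30). Among all 14849 tested genes, 2746 had an unadjusted p below 0.05. Fry with directions mixed called this list and the p53 list (fry adjusted p = 6.6e-04 and 0.0011), but it called 20 of the 23 lists. It asks only whether some members differ in either direction, so it does not set these lists apart. Of 36 DNA damage checkpoint and repair genes, 2 were lower by edgeR, while DESeq2 called 4 lower and 1 higher and limma-voom called 3 lower. Adjusted over the list alone 2 were lower and 1 was higher, with a median of -0.16 (camera adjusted p = 0.031, but adjusted p = 0.13 with an estimated correlation and 0.10 without Hnrnpl-null replicate 1). The 2 called by edgeR were Atr, a checkpoint kinase whose exons overlap a gene model, which fell from 86.4 ± 12.3 to 52.3 ± 11.7 CPM, and Trp63, which encodes the oocyte checkpoint factor p63 and went from 4.42 ± 1.20 to 1.22 ± 0.223 CPM. The Atr call was lost without WT replicate 2 or 3 or Hnrnpl-null replicate 2 (edgeR adjusted p of 0.058 to 0.11). The Trp63 call was lost without any 1 library other than Hnrnpl-null replicate 3 (edgeR adjusted p of 0.070 to 0.14). H2ax was at 40.1 ± 3.02 and 61.7 ± 16.1 CPM and was not called over all genes in the main edgeR test. Its lowest adjusted p over the alternatives was 0.0038 (edgeR, DESeq2 or limma). Among 48 hnRNP and splicing regulators 1 was higher and 1 was lower, also adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.011, but adjusted p = 0.32 with an estimated correlation and 0.18 without WT replicate 2). Esrp1, an epithelial splicing regulator, fell from 58.2 ± 5.16 to 18.7 ± 1.71 CPM. Mbnl1, a splicing regulator of the muscleblind family, rose from 46.5 ± 3.13 to 66.1 ± 7.66 CPM, but its call was lost without any 1 library other than Hnrnpl-null replicate 3 (edgeR adjusted p of 0.090 to 0.13). Hnrnpll, the closest relative of Hnrnpl, was at 28.5 ± 4.42 CPM in WT and 32.4 ± 5.20 CPM in Hnrnpl-null and was not called. Elavl2 was at 16.3 ± 5.69 and 9.70 ± 2.10 CPM and was not called in the main edgeR test. Without both Rn45s-rich libraries it was called lower (log2 fold change -1.10, edgeR adjusted p = 0.0096).

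Among somatic cell types, of 23 pregranulosa genes tested, Kitl was higher and Hes1 was lower, and adjusted over the list alone 1 was higher and 2 were lower (median -0.13, camera adjusted p = 0.10, and 0.040 without WT replicate 3). Kitl (chromosome 10, 100015821 to 100100415), the ligand of Kit, rose from 78.4 ± 7.05 to 174 ± 4.02 CPM, a log2 fold change of 1.15 ± 0.11 (edgeR adjusted p = 3.7e-05). Hes1, a target of Notch signalling, fell from 37.6 ± 3.90 to 18.8 ± 3.19 CPM. Foxl2, the transcription factor that marks granulosa cells, was at 25.6 ± 2.27 and 27.2 ± 5.69 CPM, and Irx3 was at 68.2% of WT, and neither was called in the main edgeR test. For Irx3 the lowest adjusted p over the alternatives was 0.015 (edgeR, DESeq2 or limma). Of 23 stroma and mesenchyme genes, Col1a1, Col1a2, Col3a1, Col5a1 and Dcn were higher and Gli1 was lower (11 higher and 2 lower adjusted over the list alone), with a median of 0.29 (camera adjusted p = 1.0e-07, and adjusted p = 0.038 with an estimated correlation, but 0.24 with library totals). None of these higher calls was kept by edgeR without Hnrnpl-null replicate 2, and 1 was higher without WT replicate 2 or 3 or Hnrnpl-null replicate 1 and 2 without WT replicate 1. The fibrillar collagens Col1a1 and Col5a1 rose from 2792 ± 115 to 4486 ± 218 CPM and from 432 ± 16.2 to 621 ± 32.2 CPM. Col1a1 lost its call without Hnrnpl-null replicate 2 (edgeR adjusted p = 0.054) and Col5a1, Col1a2 and Col3a1 without any 1 library other than Hnrnpl-null replicate 3 (edgeR adjusted p of 0.063 to 0.17). Dcn, the proteoglycan decorin, lost its call without any 1 library other than WT replicate 1 (edgeR adjusted p of 0.060 to 0.18). Gli1, an effector of Hedgehog signalling whose exons overlap those of Arhgap9, fell from 8.87 ± 3.29 to 3.29 ± 0.714 CPM, and its call was lost without WT replicate 2 or Hnrnpl-null replicate 1 or 2 (edgeR adjusted p of 0.084 to 0.21). Of 13 surface epithelium genes, Upk3b, Krt19 and Msln were higher (7 higher and 1 lower adjusted over the list alone), with a median of 0.48 (camera adjusted p = 1.2e-04, but adjusted p = 0.32 with an estimated correlation). Msln, the mesothelial surface protein mesothelin, rose 2.56-fold, and its call was lost without WT replicate 2 or Hnrnpl-null replicate 2 (edgeR adjusted p of 0.065 to 0.087). The calls of Upk3b and Krt19 were each lost without 4 of the 6 libraries in turn (edgeR adjusted p of 0.054 to 0.14), WT replicates 2 and 3 and Hnrnpl-null replicate 2 for both, with Hnrnpl-null replicate 1 for Upk3b and Hnrnpl-null replicate 3 for Krt19. Of 7 steroidogenic genes, Cyp11a1 and Fdx1 were higher (3 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.047, but adjusted p = 0.19 with an estimated correlation, and 0.13 and 0.091 without WT replicate 3 and Hnrnpl-null replicate 2). Cyp11a1, which cleaves the side chain of cholesterol, rose from 2.72 ± 1.21 to 11.3 ± 2.63 CPM. Fdx1 lost its call without any 1 library other than Hnrnpl-null replicate 3 (edgeR adjusted p of 0.059 to 0.14). Star was at 148% of WT and was not called in the main edgeR test, with a lowest adjusted p of 0.015 over the alternatives (edgeR, DESeq2 or limma).

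The endothelial list had 0 of 15 members called, with a median of -0.36, 5 at an unadjusted p below 0.05, and 1 higher and 2 lower by both DESeq2 and limma-voom, and adjusted over the list alone 1 was higher and 3 were lower (camera adjusted p = 0.015, but adjusted p = 0.32 with an estimated correlation and 0.16 without WT replicate 2). The endothelial cadherin Cdh5 was at 30.8 ± 7.76 and 19.7 ± 2.10 CPM, and the receptor Kdr was at 80.8 ± 3.33 and 103 ± 1.99 CPM, on opposite sides and both uncalled in the main edgeR test. Their lowest adjusted p over the alternatives was 0.011 and 0.025 (edgeR, DESeq2 or limma). Smooth muscle and pericyte genes had a median of -0.05 and a mean of 0.06, with Des called higher (2 higher and 1 lower adjusted over the list alone) among 12 tested. The Des call was lost without any 1 of the 6 libraries (edgeR adjusted p of 0.056 to 0.15). Mesonephric and ductal epithelium genes had a median of -0.30 with 0 of 8 called by edgeR, DESeq2 or limma-voom and 2 at an unadjusted p below 0.05, 0 adjusted over the list alone, and 3 of 11 lower without the 2 libraries richest in Rn45s. Sertoli and testis somatic genes had a median of 0.03 and a mean of -0.12 with Gstm6 lower among 11, as over the list alone. Camera adjusted p was 0.95, 0.31 and 0.31 for these 3 lists. The mesonephric list was called by camera without WT replicate 3 (adjusted p = 0.013) and with the replicate block (adjusted p = 0.0089). The list of dissociation stress and immediate early genes was not called (median 0.02, mean -0.05, camera adjusted p = 0.44). Within it Klf6 was higher and Egr2, Ier2 and Ccn1 were lower, and adjusted over the list alone 2 were higher and 4 lower. The Klf6, Egr2, Ier2 and Ccn1 calls were lost without 3, 2, 5 and 4 of the single libraries (edgeR adjusted p of 0.051 to 0.13), WT replicate 2 among them each time.

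**Figure D3:**
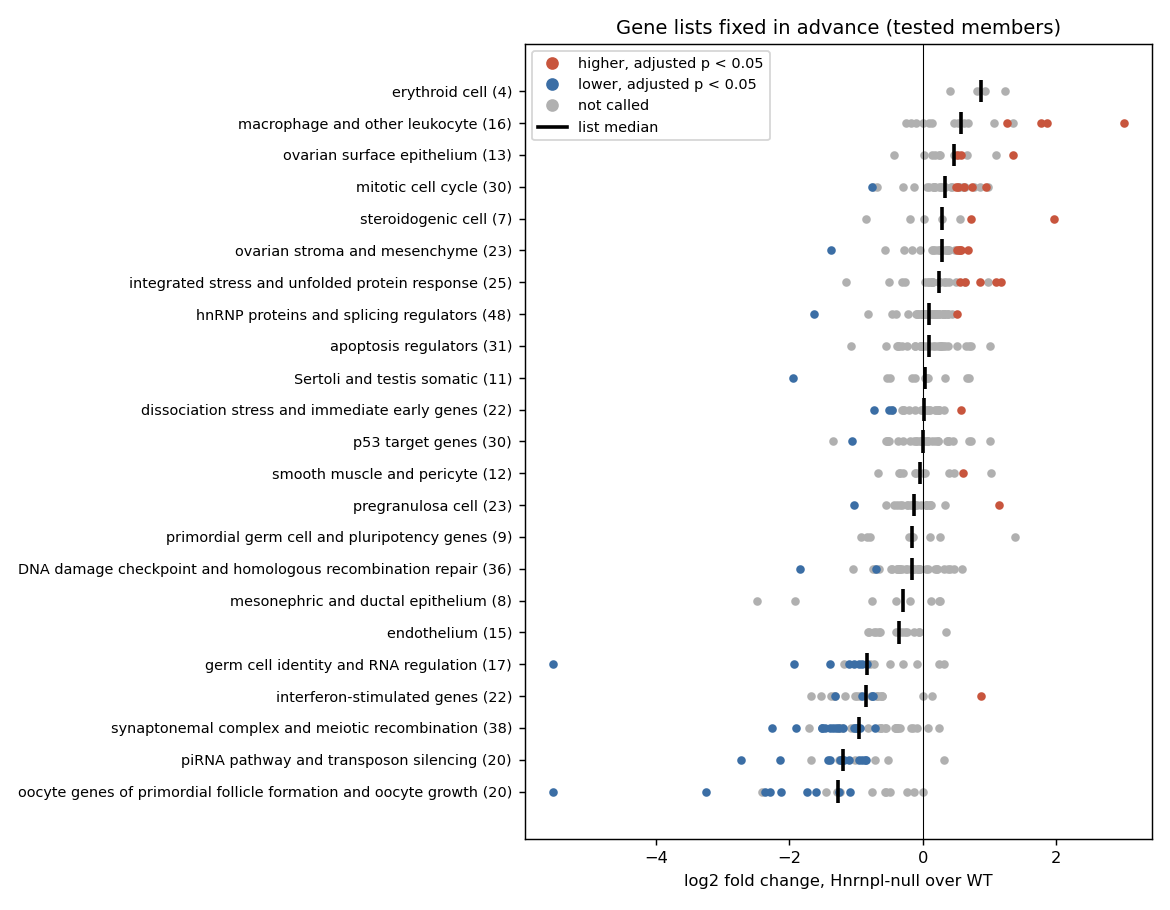
Log2 fold change of Hnrnpl-null over WT (x axis) for each tested member of the 23 gene lists fixed in advance (y axis, number of tested members in brackets). Red and blue points are genes called higher and lower by edgeR, grey points were not called and black bars are list medians, of which the lowest is -1.27 for oocyte genes of primordial follicle formation.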

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

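The settings without Rn45s, without both Rn45s-rich libraries, with halved counts and with sample weights were chosen after seeing the data. Among the 58 named genes that were called, 0 reversed in any alternative. The number of called genes moved from 663 (397 higher, 266 lower) to 1071 (645, 426) with DESeq2, 1273 (775, 498) with limma-voom, 1222 (757, 465) with voom and sample weights, 1104 (633, 471) with no filter, 301 (163, 138) with an absolute log2 fold change of at least 1, and 236 (147, 89) at an adjusted p below 0.01. Halved counts gave 812 (465, 347) of 13572 genes tested, and 643 of them were among the 663. Library totals without a composition factor gave 4 (3, 1), since Rn45s sets those totals, and 255 (123, 132) when Rn45s was left out of them, a split of 48.2% higher against 59.9% in the main test. Leaving out 1 library gave between 249 and 853 calls, 145 to 532 higher and 104 to 321 lower; the lowest total came without Hnrnpl-null replicate 2, the other totals were 370, 257 and 335 without WT replicates 1, 2 and 3 and 389 without Hnrnpl-null replicate 1, and the highest came without Hnrnpl-null replicate 3, the library with the fewest counts outside Rn45s. Of 58 named called genes, 54 lost the call with library totals, 17 with totals without Rn45s, between 5 and 17 without 1 library, and 3 (Kif17, Kbtbd11 and Trp63) without both Rn45s-rich libraries. The cause was not tested beyond the scaling. Hnrnpl stayed uncalled in all 23 alternatives (log2 fold change 0.07 to 0.25, edgeR, DESeq2 or limma adjusted p of 0.41 or more). Of 23 lists tested, 15 were called with the preset correlation, 8 with an estimated one, 11 by directional fry and 20 by fry with directions mixed. The 4 germ cell lists and those of interferon, mitosis and leukocytes (7 in all) were called in all 16 other settings. Directional fry kept the DNA damage, integrated stress and steroidogenic lists (fry adjusted p of 0.012, 0.021 and 0.021). Mixed fry also called lists that camera did not, p53 targets and apoptosis regulators among them. The deviations of same-numbered libraries correlated at -0.12, 0.09 and -0.09. These values give no sign of a pairing by replicate number, but with 3 libraries per group they cannot exclude one. With the replicate block edgeR called 444 genes (265, 179), or 508 with the length trend also removed. With that block camera called 16 lists, adding the mesonephric and ductal epithelium list (camera adjusted p = 0.0089). Normalization without mitochondrial and haemoglobin genes changed nothing, since mitochondrial genes are absent and the adult globin genes are listed at 0. In simulation with the count totals, dispersions and number of these libraries, 14.9% of 1.5-fold changes were called. Those totals overstate the fragments, so the share for these data may differ.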

Other observations

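The tests of other cell sources below were planned before their values were seen, while the gene lists used for them and the test of an equal loss were set after the main result was seen. Mast cell genes were a further group higher in the libraries labelled Hnrnpl-null. Of 14 tested genes in an added mast cell list, 12 were higher, with a median log2 fold change of 2.31. Leaving out 1 library gave 9 to 13 higher, the lowest without WT replicate 2. The summed level of all 18 genes of the list was 200 ± 2.88 CPM in WT and 1000.3 ± 71.2 CPM in Hnrnpl-null (SD, n = 3 each). The chymase Cma1 rose from 40.1 ± 4.64 to 281 ± 18.2 CPM, the carboxypeptidase Cpa3 5.55-fold to 132 ± 3.34 CPM, the tryptase Tpsb2 from 59.8 ± 6.35 to 286 ± 53.3 CPM and Mcpt4 from 5.29 ± 0.829 to 61.4 ± 19.4 CPM. Hdc, which makes histamine, rose from 28.8 ± 1.66 to 116 ± 15.2 CPM. Mast cell genes were thus present in WT, while the 8 largest rises, all in an added list of granulocyte-monocyte progenitor genes, were at 0.843 CPM (Prtn3) or lower there by mean. Reln, which encodes reelin, fell from 51.5 ± 1.43 to 15.5 ± 0.552 CPM and lies in no list.

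The added list of granulocyte-monocyte progenitor genes, which holds the 8 largest rises, had 13 of 18 members higher, with a summed level of 25.3 ± 2.47 CPM in WT and 707 ± 95.4 CPM in Hnrnpl-null, and 15 higher without both Rn45s-rich libraries. Leaving out 1 library gave 12 to 15 higher, the lowest without WT replicate 2 or 3 or Hnrnpl-null replicate 2. Tissue carried over with the ovary is a candidate explanation. Fetal liver tissue would bring hepatocyte transcripts, but Alb, Afp and Apoa1 together reached at most 0.0323% of the Mpo level in a Hnrnpl-null library. Blood or marrow would bring mature neutrophils, but S100a8, S100a9, Ngp, Camp and Ltf together reached at most 1.73% of Mpo, and the 7 tested members of the neutrophil list had a median of -1.28 (0 called by edgeR, 3 at an unadjusted p below 0.05, 1 lower by DESeq2, 3 lower by limma-voom and 1 lower by edgeR without Hnrnpl-null replicate 1). The erythroid list, also of blood, had a median of 0.88 (camera adjusted p = 0.019, but adjusted p = 0.32 with an estimated correlation). Its 4 tested members had 0 called by edgeR, while DESeq2 and limma-voom each called 2 higher, so some carried-over blood stays open. Bone tissue would bring osteoblast genes, of which 4 of the 9 listed were tested. Their median log2 fold change was -0.78, with an SD over the 4 genes of 0.455. That SD holds no error between libraries. Progenitor cells free of these tissues, a mixture with another myeloid library, and a difference in the ovaries that goes with the genotype label stay open and were not tested. The megakaryocyte and lymphoid lists had 4 tested members each (medians 0.33 and 1.21), with 0 called by edgeR, 2 and 1 at an unadjusted p below 0.05, and 2 lymphoid genes higher by DESeq2. Of the hepatocyte list 1 member was tested and not called.

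Fewer germ cells, and so an equal loss of all germ cell transcripts, is a candidate explanation of the lower germ cell genes. With the median fall of the germ cell identity list (log2 -0.84) set as the expected change, 13 of 88 members of the 4 germ cell lists fell below it (edgeR, adjusted over the members), among them Nobox, Lhx8, Sohlh1, Tdrd1, Piwil2, Sycp3 and Rec8, and 3 lay above it. That median comes from genes that were themselves among the tested members, its error was not counted, and expression in somatic cells can shrink a fall, so an equal loss stays open, as do lower transcript levels within germ cells and a different developmental stage. The 2 Rn45s-rich libraries are argued against as the source, since the median over the members was -1.037 without them and -1.03 with them. A trend with gene length is argued against in the same way, with a median of -1.029 after its removal.

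With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be had. Of the 10 splits, 1, the real one, gave as many as 663 genes, and the highest other gave 0 by edgeR, with 186 to 717 genes at an unadjusted p below 0.05 against 2746. A genome segment that travels with the targeted allele was tested as a source of calls. Of 269 tested genes within 10 Mb of Hnrnpl on chromosome 7, 6 (2.23%) were called, against 4.51% elsewhere (two-sided Fisher's exact test, p = 0.074, odds ratio 0.483 with a 95% interval of 0.175 to 1.07), which is argued against as a source of more calls near the gene.

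In WT replicate 1, 16 genes were at over 20 CPM of the counts outside Rn45s and over 10 times the highest other library plus 1, and they took 6.40% of its counts outside Rn45s, Kif17, Eif4ebp2, Chd3 and Zfhx4 among them. Lars2 took 2.06% and 2.59% of all counts in the 2 Rn45s-rich libraries and 0.313% to 0.963% in the others, at 1.31 to 3.01 counts per 100 of Rn45s in all 6.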
